A study of Mus musculus with 6 samples.

How the data were processed

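RNA was sequenced from 6 whole tumors, 3 labelled NTC and 3 labelled Gli2CA. Per the labels' protocols, RNA was extracted with a column kit, messenger RNA was selected with poly-T beads and fragmented, and libraries were made with random hexamer priming. The deposited table gives FPKM (fragments per kilobase of transcript, scaled by the fragments of each sample) for 54532 mouse genes in each of the 6 samples, and the authors' aligner, counting tool, genome build, annotation and strand setting are not given in the sources used here. Each column was matched to its sample by its name, and groups and replicate numbers came from the sample titles. Ensembl identifiers were joined to symbols and to GENCODE M21 gene models on GRCm38, which gave a symbol and a length for 54409 genes. Coordinates in the text are those of GENCODE M21.

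The FPKM values kept the number of fragments behind them. Each value multiplied by the mean length of the gene's annotated transcripts was a whole multiple of 1 step per sample, within 0.1 fragment, for 97.3% of tested low values of genes with several transcripts and 99.7% for genes with 1 transcript, where chance gives 20%. With the union of exons as length, 20.7% came out whole. The recovered fragments summed to between 0.994 and 0.999 of the totals from the steps, which ran from 16223343 to 22271678 per sample. As the length behind FPKM is a mean over annotated transcripts, levels of different genes are not compared. No pair of libraries was alike within sampling noise: the mean chi-square per gene between pairs was at least 49.4, where about 1 is noise. Correlations of log2 values were 0.94 to 0.975 within groups and 0.883 to 0.961 between groups, and the first principal component held 47.5% of the variance.

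The main test was limma 3.58.1 (lmFit, then eBayes with a variance trend) in R 4.3.3 on log2(FPKM + 0.5), for the 15820 genes with a mean FPKM of at least 0.5 over the 6 samples, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low genes. Every adjusted p of a gene comes from this limma fit unless an alternative is named. The 29 gene lists were tested with camera at a preset correlation between genes of 0.01, with adjustment over the lists. The count adjusted over all genes and the count adjusted over the list alone are given for each, from limma unless limma-voom is named. Counts of members with an unadjusted p under 0.05 are to be read against 4355 of the 15820 tested genes at that level in limma. Camera with the correlation estimated from the data and fry were run beside it. Because only FPKM was deposited, no count model was the main result, and limma-voom on the recovered fragments was an alternative added after seeing the data.

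Genes were named by a rule. It takes Gli2, Gli1, Ptch1 and Hhip, the 10 highest and 10 lowest log2 fold changes among called genes with the groups fully separated, leaving out symbols of predicted genes and receptor segments, and up to 4 members per list with the smallest p, or 6 for Wnt ligands and prostaglandin genes. Foxf1, Foxl1, Spp1, Dkk2, Pfkfb3, Csf1, Cd3d, Gzma, Klrk1, Gzmb, Prf1, Ptprc, Acta1, Adipoq, Tyr, Tyrp1, Dct and the genes named in the last part of the text but outside this rule were chosen after their values were seen.

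The analysis was tested on simulated data made from the means and depths of these 6 libraries. In a simulated comparison of 3 against 3 with 15795 genes tested, 30.6% of genes changed by 2-fold and 83% of genes changed by 4-fold were called, 14% of 136 calls were unchanged genes, and 4.86% of unchanged genes had a p under 0.05. A shifted list had a camera adjusted p of 3.1e-21 and an unshifted list one of 0.95. Genes were drawn independently, each with a spread typical of its expression level. The simulated comparison held no correlation between genes and no length trend between libraries. These rates and list results therefore need not hold for the real libraries. Gene counts at the threshold can therefore miss many 2-fold changes, and more of the calls than the nominal 5% can be unchanged genes.

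The test, the gene lists, the naming rule and the first set of alternatives were fixed before the data were examined. These alternatives were pseudocounts of 1 and 0.1, a filter at a mean FPKM of 1 and none, median-ratio and quantile scaling, sample weights, no variance trend, robust eBayes, protein-coding genes alone rescaled, a replicate block, each sample left out, and for lists an estimated correlation, fry and ranks. Limma-voom and the removal of a gene length or GC trend per sample were added after seeing the data. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.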

Results

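Bulk RNA sequencing was carried out on whole mouse melanomas grown from a cell line that carries an activating BRAF mutation. The cells held either a non-targeted control (NTC) or an active form of Gli2 (Gli2CA), a transcription factor of the Hedgehog pathway, and 1000000 cells in 100 uL of matrigel and saline were implanted in C57Bl/6 mice. Tumors were harvested at day 28, with 3 samples per group. Whole tumors hold host stroma, vessels and immune cells beside the melanoma cells. The totals of fragments computed back from the FPKM values were 22271678, 21132722 and 17719562 in NTC replicates 1, 2 and 3, and 19647469, 16223343 and 20180385 in Gli2CA replicates 1, 2 and 3. The labels do not state that each sample came from a separate mouse, so the p-values measure the spread between these samples, which may be technical in part.

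Gli2 itself was lower in every tumor labelled Gli2CA than in every NTC tumor, which goes against the label. Gli2 (ENSMUSG00000048402, chromosome 1, 118834132 to 119053619, minus strand, GENCODE M21 on GRCm38) stood at 8.88, 11.1 and 7.96 FPKM in NTC replicates 1 to 3 and at 3.21, 5.82 and 1.61 FPKM in Gli2CA replicates 1 to 3. These values came from 310, 367 and 221 fragments against 99, 148 and 51. Its log2 fold change was -1.40 (SE 0.38, n = 3 per group), with an adjusted p of 0.0853 in limma, short of the threshold. It passed in 3 of 20 alternatives, with sample weights (0.0211), with protein-coding genes alone, rescaled (0.0425), and with a replicate block (0.03). Whether transcripts of the introduced construct would be counted under the mouse Gli2 gene is not given in the sources used here. For this reason the groups are called by their labels throughout, and each direction below is that of the tumors labelled Gli2CA against those labelled NTC.

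Of the 29 tested genes of the Hedgehog list, 22 had negative estimates in the tumors labelled Gli2CA. Ptch1, the Hedgehog receptor and a direct Gli target, averaged 20.3 ± 10.8 FPKM in NTC and 7.25 ± 3.38 FPKM in Gli2CA (SD, n = 3 each; log2 fold change -1.39, SE 0.41, adjusted p = 0.093), and passed in the same 3 alternatives as Gli2 (0.024, 0.0479 and 0.0257). Gli1, another direct target, overlapped between the groups at 9.81 ± 6.24 and 5.07 ± 4.94 FPKM (SD, n = 3 each; adjusted p = 0.271). Hhip, a Hedgehog-binding decoy receptor, lay under the expression filter at 0.447, 0.702 and 1.17 FPKM in NTC and 0.06, 0.409 and 0.087 FPKM in Gli2CA. Of the 29 tested members of the Hedgehog and Gli target list, 0 passed over all genes in limma, 0 in limma-voom and 15 had an unadjusted p under 0.05 in either, 12 lower and 3 higher, and 5 were lower when adjusted over the list alone, among them Dhh at a log2 fold change of -0.83 (SE 0.23) and Ccnd2 at -0.90 (SE 0.27). The 3 higher genes were Foxf1 at 0.98 (SE 0.33), Foxl1 at 1.05 (SE 0.36) and Spp1 at 1.03 (SE 0.41), with adjusted p of 0.113, 0.115 and 0.151. The list had a median log2 fold change of -0.55 and passed camera (adjusted p = 0.014), with an adjusted p = 0.66 with an estimated correlation. Its call was also lost with the gene length trend between the libraries removed (adjusted p = 0.11), with the GC trend removed (0.088) and with protein-coding genes alone, rescaled (0.075).

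**Figure D1:**
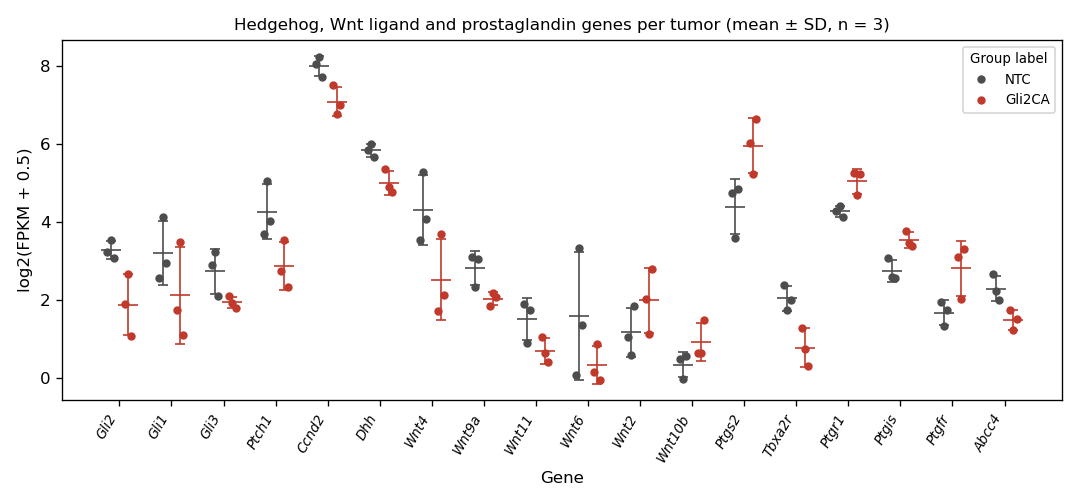
Values of Hedgehog, Wnt ligand and prostaglandin genes on the vertical axis as log2(FPKM + 0.5), with 1 point per tumor and the mean ± SD of 3 tumors per group label, NTC in grey and Gli2CA in red. Gli2 was lower in all 3 tumors labelled Gli2CA than in all 3 NTC tumors, and Ptgs2 was higher in all 3.

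Across all genes, 3 of the genes called higher in the tumors labelled Gli2CA belong to the hypoxia list. Of 15820 genes tested, 55 passed an adjusted p of 0.05 in limma, 42 higher and 13 lower in the tumors labelled Gli2CA. This balance depended on the threshold and the setting: at an adjusted p under 0.1 there were 791 higher and 969 lower, and at 0.05 there were 704 and 884 with sample weights, 901 and 1027 with a replicate block, 106 and 631 with protein-coding genes rescaled and 51 and 49 with limma-voom. A further measure of spread was that 5345 genes, or 33.8% of those tested, had all samples of one group above all samples of the other, where chance gives 10%. Genes are not independent of each other, so the excess of this share over 10% is not a test of the labels. All 55 called genes were separated in this way, which a call with 3 samples per group makes likely and which adds no support. The count rested on single libraries: it was 7, 4 and 18 without NTC replicates 1, 2 and 3, and 9, 97 and 6 without Gli2CA replicates 1, 2 and 3. All 55 genes kept their direction in each of these fits. Only 3 of them passed in all 6, Gm773, Gm11884 and 3830403N18Rik, all higher in the tumors labelled Gli2CA (adjusted p = 0.000317, 0.000779 and 0.00118 with all libraries), and these were picked out after their values were seen. Gm773 and 3830403N18Rik are annotated as protein-coding genes and Gm11884 as a long noncoding RNA gene.

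Crabp1, a cytoplasmic retinoic acid binding protein, rose from 4.32 ± 2.43 to 168 ± 151 FPKM (SD, n = 3 each; log2 fold change 4.72, SE 0.71, adjusted p = 0.0385). Cck, which encodes the peptide hormone cholecystokinin, rose from 0.218 ± 0.152 to 20.6 ± 15.1 FPKM (log2 fold change 4.44, SE 0.68, adjusted p = 0.0406), from 5, 1 and 2 fragments in the NTC tumors to 298, 35 and 386. Crct1 (cysteine-rich C-terminal 1) and Lgals7, the keratinocyte galectin-7, also rose. Crct1 had a log2 fold change of 3.27 (SE 0.48), and Lgals7 went from 34.6 ± 5.89 to 330.1 ± 202 FPKM (SD, n = 3 each; adjusted p = 0.0438). Of 7 keratinocyte and epithelial markers, 3 were higher in all 3 tumors labelled Gli2CA without passing, with Krt14 at a log2 fold change of 4.10 (SE 0.78, adjusted p = 0.0565), Pkp1 at 13.7 ± 8.84 and 56.4 ± 42.8 FPKM (SD, n = 3 each; adjusted p = 0.102) and Krt10 at 0.99 (SE 0.45, adjusted p = 0.19). The other 4 had negative estimates, Cdh1 at -1.06 (SE 0.33, adjusted p = 0.101) among them. Slfn4, a myeloid Schlafen gene, rose by 2.97 on the log2 scale (SE 0.47), Syt8, a synaptotagmin, by 2.70 (SE 0.34) and Odf2l by 2.56 (SE 0.34). The small Cajal body RNA gene Scarna17 was called at 2.81 (SE 0.38), on only 18 fragments in Gli2CA and 1 in NTC. Their ratio adjusted for depth was 19.6, with an exact 95% interval for counting error of 3.1 to 818. Each of these calls was lost in at least 5 of the 6 fits without 1 library. Without Gli2CA replicate 3 the adjusted p of the 8 genes ran from 0.0924 to 0.168, and without NTC replicate 1 from 0.12 to 0.16. Without NTC replicate 2 only Scarna17 passed (0.0408), without Gli2CA replicate 1 only Crct1 (0.0199), without Gli2CA replicate 2 Crabp1, Cck, Lgals7, Syt8 and Odf2l (0.0024 to 0.0205), and without NTC replicate 3 none (0.0625 to 0.0673).

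Bnip3, a mitochondrial protein induced by low oxygen, rose from 102 ± 17.7 to 589.7 ± 116 FPKM (SD, n = 3 each; log2 fold change 2.52, SE 0.25, adjusted p = 0.0117). Ankrd37, another target of hypoxia-inducible factor, rose from 10.1 ± 3.21 to 64.2 ± 13.2 FPKM (2.63, SE 0.28, adjusted p = 0.0117). Higd1a, a hypoxia-induced mitochondrial protein, rose from 72.3 ± 3.56 to 256 ± 52.4 FPKM (1.80, SE 0.23, adjusted p = 0.0225). Of the 20 tested members of the hypoxia and glycolysis list these 3 were higher over all genes, and 5 were higher and 1 lower when adjusted over the list alone. Car9, a carbonic anhydrase of the hypoxia response, had a log2 fold change of 1.97 (SE 0.37, adjusted p = 0.0551), and the glycolytic regulator Pfkfb3 one of -1.09 (SE 0.28, adjusted p = 0.0798). The list passed camera with a median of 0.61 (adjusted p = 2e-04), and had an adjusted p = 0.66 with an estimated correlation. It passed in 21 of 23 alternatives, all 6 fits without 1 library among them, but not with fry (adjusted p = 0.16). Its median ran from 0.33 to 0.84 over the settings. The mean log2 value of the list, relative to the NTC mean, was 0.28, -0.18 and -0.1 in NTC replicates 1 to 3. In Gli2CA replicates 1 to 3 it was 1.31, 0.55 and 0.57, so the size of the change was largest in Gli2CA replicate 1. Among the 6 fits without 1 library, the Bnip3 call was lost only without NTC replicate 2 (adjusted p = 0.0684). The Ankrd37 call was lost without NTC replicate 1 (0.0736) or 2 (0.0684). Over all 20 alternatives for genes, Bnip3 passed in 18, Ankrd37 in 17 and Higd1a in 14. Of the 6 fits without 1 library, Higd1a passed only without Gli2CA replicate 2 (0.0238) and stood at 0.0567 to 0.127 in the other 5.

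The gene with the strongest decrease was Soga3, at 8.30 ± 1.99 FPKM in NTC and 0.439 ± 0.358 FPKM in Gli2CA (SD, n = 3 each; log2 fold change -3.26, SE 0.34, adjusted p = 0.0117). Xirp1, an actin-binding protein of striated muscle, fell by 2.39 on the log2 scale (SE 0.28, adjusted p = 0.0175). P3h2, a collagen prolyl 3-hydroxylase, fell by 2.17 (SE 0.30, adjusted p = 0.0328). Tlr12, a Toll-like receptor that senses profilin, fell by 1.96 (SE 0.31), the sialyltransferase gene St8sia6 fell by 1.88 (SE 0.27), and the death receptor gene Tnfrsf21 fell by 1.71 (SE 0.26). Egflam, which encodes pikachurin, went from 215 ± 41.4 to 66.6 ± 11.7 FPKM. The metalloproteinase gene Adamts1 went from 405.7 ± 96.7 to 128 ± 22.8 FPKM, and the transglutaminase gene Tgm2 from 269.6 ± 36.6 to 98.1 ± 18.3 FPKM (SD, n = 3 each). Efna5, an ephrin ligand, fell by 1.65 (SE 0.24, adjusted p = 0.0356). Among the 6 fits without 1 library, the Soga3 call was lost without NTC replicate 1 (0.0736), NTC replicate 2 (0.0684) or Gli2CA replicate 3 (0.0611). In the same 6 fits Xirp1 passed only without NTC replicate 3 (0.0225) or Gli2CA replicate 2 (0.0256). Over all 20 alternatives Soga3 passed in 16 and Xirp1 in 15. For the other 8 genes the adjusted p was 0.0736 to 0.16 without NTC replicate 1, 0.127 to 0.142 without NTC replicate 2, 0.0539 to 0.0593 without Gli2CA replicate 1 and 0.131 to 0.212 without Gli2CA replicate 3. Without NTC replicate 3 only P3h2 passed (0.0172), and without Gli2CA replicate 2 St8sia6, Egflam and Efna5 did (0.0295 to 0.0481).

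**Figure D2:**
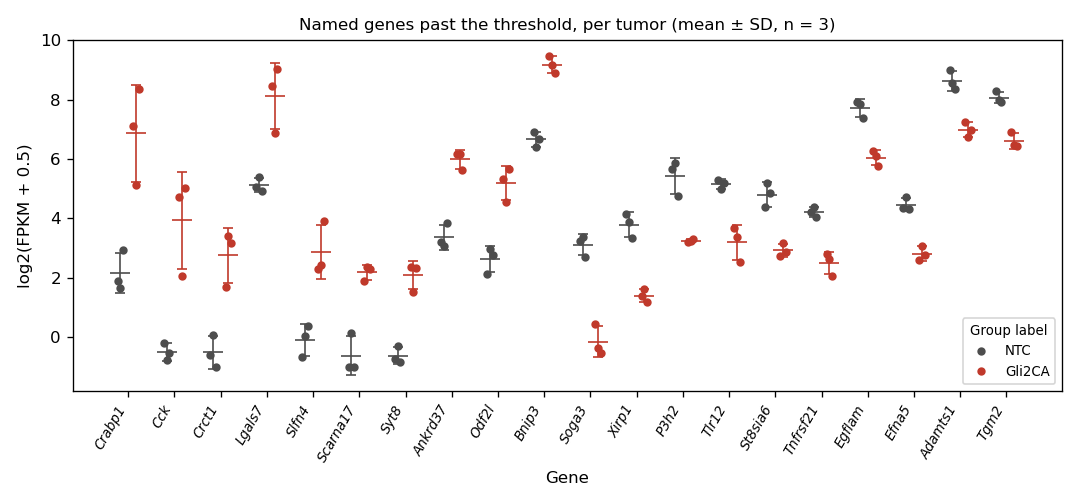
The 20 genes named by the rule as highest and lowest among those past the threshold, as log2(FPKM + 0.5) on the vertical axis, with 1 point per tumor and the mean ± SD of 3 tumors per group label, NTC in grey and Gli2CA in red. For each gene the 3 tumors of one label lie above the 3 of the other.

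The title of the series names Wnt ligands, and of 11 tested Wnt ligand genes 0 passed in limma, either over all genes or adjusted over the list alone. Limma-voom also gave 0, and 3 ligand genes had an unadjusted p under 0.05 in either tool, all lower. That is near the share over all tested genes, 4355 of 15820 in limma. Wnt4 averaged 22.0 ± 14.5 FPKM in NTC and 6.36 ± 5.29 FPKM in Gli2CA (SD, n = 3 each; log2 fold change -1.79, SE 0.57, adjusted p = 0.101). Wnt9a stood at a log2 fold change of -0.80 (SE 0.28, adjusted p = 0.12), Wnt11 at -0.81 (SE 0.35) and Wnt6 at -1.26 (SE 0.71), while Wnt2 and Wnt10b had values of 0.82 (SE 0.47) and 0.57 (SE 0.35). The list had a median of -0.22 and a camera adjusted p of 0.4. Another 8 ligand genes lay under the filter. Wnt receptors, secretion factors and secreted modulators had 26 tested members, of which 0 passed over all genes (12 at an unadjusted p under 0.05) and 1 was higher and 9 were lower when adjusted over the list alone. The co-receptor gene Lrp6 had a log2 fold change of -1.17 (SE 0.28, adjusted p = 0.071), Ror2 of -1.08 (SE 0.27) and the Frizzled receptor genes Fzd2 and Fzd4 of -1.19 (SE 0.31) and -1.08 (SE 0.29). The 1 higher gene was Dkk2, a secreted Wnt modulator, with the largest change of the list at 2.86 (SE 0.80, adjusted p = 0.0874). The list passed camera (median -0.64, adjusted p = 0.0017), had an adjusted p = 0.52 with an estimated correlation, and lost its call with the gene length trend removed (adjusted p = 0.091). It was 1 of 2 lists that passed fry, a test of whether a list's genes move one way on balance (adjusted p = 0.049). Of 15 tested Wnt and beta-catenin target genes, 0 passed over all genes (3 at an unadjusted p under 0.05), and 1 was higher and 2 were lower when adjusted over the list alone (camera adjusted p = 0.32). The lower genes were Axin2, a feedback inhibitor of the pathway, at -1.23 (SE 0.27, adjusted p = 0.0679), and Lef1, at 7.55 and 3.41 FPKM on average (adjusted p = 0.093). The higher gene was Myc at 0.73 (SE 0.21, adjusted p = 0.089).

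Prostaglandin signalling, which the title also names, gave 0 of 21 tested genes past the threshold in limma, over all genes or adjusted over the list alone. Limma-voom gave 0 as well, and 9 genes had an unadjusted p under 0.05 in either tool, 5 higher and 4 lower. Ptgs2, which encodes the inducible cyclooxygenase COX-2, averaged 21.9 ± 9.15 FPKM in NTC and 66.4 ± 30.7 FPKM in Gli2CA (SD, n = 3 each). Its log2 fold change was 1.57 (SE 0.43, adjusted p = 0.085) and all 3 tumors labelled Gli2CA lay above all 3 NTC tumors. The thromboxane receptor gene Tbxa2r had a log2 fold change of -1.26 (SE 0.33, adjusted p = 0.0806) and the prostaglandin exporter gene Abcc4 one of -0.80 (SE 0.28). Ptgr1, Ptgis, the prostacyclin synthase gene, and Ptgfr had values of 0.78 (SE 0.23), 0.79 (SE 0.24) and 1.13 (SE 0.37). The camera adjusted p was 0.9, and the list's median of -0.13, its mean of -0.01 and its camera direction, upward, differed in sign.

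Neutrophil chemoattractants and granulopoietic cytokines were higher as a list in the tumors labelled Gli2CA. Of its 11 tested members 0 passed over all genes (6 at an unadjusted p under 0.05), and 4 were higher and 1 lower when adjusted over the list alone. The lower gene was Csf1 at a log2 fold change of -0.97 (SE 0.33, adjusted p = 0.115). Another 4 genes of the list were not tested. Il6 stood at 0.465 ± 0.248 against 4.17 ± 2.82 FPKM (SD, n = 3 each; log2 fold change 2.14, SE 0.43, adjusted p = 0.0632). Cxcl1 stood at 1.38 on the log2 scale (SE 0.28, adjusted p = 0.0632), Il11 at 1.85 (SE 0.50) and Mif at 0.95 (SE 0.25). Cxcl1 was low in both groups, at 0.888 FPKM in NTC and 3.14 FPKM in Gli2CA on average. The list passed camera (median 0.95, adjusted p = 0.0075) and fry (adjusted p = 0.049), with an adjusted p = 0.52 with an estimated correlation. It passed in 22 of 23 alternatives, though with the gene length trend removed the median fell to 0.44 (camera adjusted p = 0.036). Of 18 tested neutrophil markers, 0 passed over all genes (4 at an unadjusted p under 0.05) and 2 were higher when adjusted over the list alone (camera adjusted p = 0.22; 0.0086 without NTC replicate 1). Among them Trem1 had a log2 fold change of 1.42 (SE 0.32, adjusted p = 0.0679), Clec4d of 1.25 (SE 0.32), S100a8 of 1.21 (SE 0.51) and Csf3r of -0.66 (SE 0.28). Of 26 tested macrophage and monocyte markers, 0 passed over all genes (9 at an unadjusted p under 0.05), and 1 was higher and 3 were lower when adjusted over the list alone (camera adjusted p = 0.25; 0.014 without NTC replicate 2). Csf1r, the macrophage growth factor receptor gene, averaged 93.1 ± 20.9 and 35.0 ± 13.1 FPKM (SD, n = 3 each; log2 fold change -1.43, SE 0.29, adjusted p = 0.0642). Cx3cr1 had a log2 fold change of -1.30 (SE 0.26), Apoe of -1.24 (SE 0.31) and Arg1, arginase 1, of 1.83 (SE 0.51).

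Markers of T cells and type 1 dendritic cells and genes of antigen presentation were lower as lists, and no single member passed over all genes in limma. Limma-voom gave 1 type 1 dendritic cell gene, Wdfy4 (log2 fold change -1.43, adjusted p = 0.0477), and 0 in the other 4 lists. Of 31 tested T cell, cytotoxic lymphocyte and natural killer cell genes, 0 passed over all genes (15 at an unadjusted p under 0.05) and 7 were lower when adjusted over the list alone, with a median of -0.70 (camera adjusted p = 0.00073; adjusted p = 0.66 with an estimated correlation). Il2rb was at -1.43 (SE 0.29, adjusted p = 0.0636), Cd3e at -1.31 (SE 0.28), Cd4 at -1.49 (SE 0.33) and Trac at -1.39 (SE 0.33). Of the 31 genes 23 had negative and 8 positive estimates, with Cd3d among the positive ones at 0.33 (SE 0.49). Genes of cytotoxic and natural killer cells went both ways. Gzma was at 0.65 (SE 0.50), Klrk1 at 0.14 (SE 0.30) and Gzmb at 0.11 (SE 0.31), while Prf1 was at -1.03 (SE 0.37). Conventional type 1 dendritic cell markers had 15 tested members, 0 past the threshold over all genes (8 at an unadjusted p under 0.05) and 5 lower when adjusted over the list alone (median -0.73, camera adjusted p = 0.00043; adjusted p = 0.66 with an estimated correlation). Wdfy4 was at -1.29 (SE 0.24, adjusted p = 0.0541) and Irf8 at -0.74 (SE 0.23). All 10 MHC class II genes had negative estimates, 0 passed over all genes (7 at an unadjusted p under 0.05) and 7 were lower when adjusted over the list alone (median -0.88, camera adjusted p = 0.00043; adjusted p = 0.66 with an estimated correlation). Cd74, the invariant chain, averaged 4006 ± 816 FPKM in NTC and 1393 ± 582 FPKM in Gli2CA (SD, n = 3 each; adjusted p = 0.0692), and Ciita, the class II transactivator, had a log2 fold change of -1.18 (SE 0.28). Of 30 MHC class I and interferon-gamma response genes, 0 passed over all genes (12 at an unadjusted p under 0.05) and 6 were lower when adjusted over the list alone (median -0.39, camera adjusted p = 0.00073; adjusted p = 0.66 with an estimated correlation), with the peptide transporter gene Tap2 at -1.17 (SE 0.25) and Tapbp at -1.02 (SE 0.27). Regulatory T cell and checkpoint genes gave 0 of 23 over all genes (11 at an unadjusted p under 0.05) and 9 lower when adjusted over the list alone (median -0.62, camera adjusted p = 0.00076; adjusted p = 0.66 with an estimated correlation). Tigit was at -1.40 (SE 0.26, adjusted p = 0.0541), Lag3 at -1.28 (SE 0.29) and Foxp3 at -1.17 (SE 0.31). Without NTC replicate 3 the T cell list and the MHC class I list lost their calls, at adjusted p of 0.07 and 0.062. Ptprc, which encodes the leukocyte antigen CD45, was at 81.0 ± 17.3 and 85.1 ± 5.71 FPKM (SD, n = 3 each; log2 fold change 0.09, SE 0.23). Of 20 genes shared by most leukocytes, a list chosen after the data were seen and from which Ptprc was left out because its value was already known, 18 had negative estimates, with a median of -0.72, 0 past the threshold over all genes and 11 lower when adjusted over the list alone.

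Type I interferon response genes went the other way as a list. Of 25 tested members 0 passed, over all genes or adjusted over the list alone (10 at an unadjusted p under 0.05), and the list passed camera (median 0.49, adjusted p = 0.0037), with an adjusted p = 0.66 with an estimated correlation. Ifi27l2a averaged 129.8 ± 62.0 and 633.6 ± 374 FPKM (SD, n = 3 each; log2 fold change 2.23, SE 0.52, adjusted p = 0.0692). Isg15 had a log2 fold change of 1.19 (SE 0.36), Rsad2 of 0.98 (SE 0.32) and Oasl2 of -0.69 (SE 0.24). Without Gli2CA replicate 3 the call was lost (adjusted p = 0.13). Of 9 tested B cell and plasma cell markers, 1 was lower over all genes and adjusted over the list alone (camera adjusted p = 0.42). This was Cd22, an inhibitory receptor of B cells, which fell by 1.44 on the log2 scale (SE 0.23, adjusted p = 0.0438). Cd22 passed without Gli2CA replicate 2 (0.0405) and stood at 0.0642 to 0.204 without any other library. Of 17 type 2 and mature dendritic cell markers, 0 passed over all genes or adjusted over the list alone, 5 had an unadjusted p under 0.05 (camera adjusted p = 0.14; 0.028 without NTC replicate 2), with Itgax at -1.05 (SE 0.28) and Ccl22 at -1.03 (SE 0.36).

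Cell cycle genes were higher as a list, though not in every tumor labelled Gli2CA, and endothelial genes were lower. Of 31 cell cycle genes 29 had positive estimates, 0 passed over all genes (12 at an unadjusted p under 0.05) and 3 were higher when adjusted over the list alone, with a median of 0.62 (camera adjusted p = 0.00022; adjusted p = 0.66 with an estimated correlation). The mean log2 value of the list, relative to the NTC mean, was -0.39, 0.31 and 0.08 in NTC replicates 1 to 3 and 0.85, -0.10 and 1.07 in Gli2CA replicates 1 to 3, so Gli2CA replicate 2 lay among the NTC tumors. The median ran from 0.28 without Gli2CA replicate 3 to 1.01 without Gli2CA replicate 2 (camera adjusted p = 0.0046 and 9.8e-11). It was 0.41 without NTC replicate 1. The centromere protein gene Cenpa stood at 25.6 ± 10.5 against 73.9 ± 15.3 FPKM (SD, n = 3 each; log2 fold change 1.59, SE 0.35, adjusted p = 0.0664), Rrm2 at 1.21 (SE 0.30) and Birc5 at 1.44 (SE 0.37). Of 22 endothelial and pericyte genes 0 passed over all genes (12 at an unadjusted p under 0.05) and 6 were lower when adjusted over the list alone (median -0.84, camera adjusted p = 0.00022; adjusted p = 0.66 with an estimated correlation). Plvap was at -1.16 (SE 0.28, adjusted p = 0.0729), the cadherin gene Cdh5 at -1.15 (SE 0.28) and the VEGF receptor gene Kdr at -1.01 (SE 0.26). Both lists passed in 21 of 23 alternatives, most of which were camera at the same preset correlation. Both calls were lost with the estimated correlation and with fry (fry adjusted p = 0.38 for cell cycle and 0.16 for endothelial genes).

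Matrix, mesenchymal and melanocyte genes had lower medians and calls that were more easily lost. Extracellular matrix and fibroblast genes gave 0 of 27 over all genes (9 at an unadjusted p under 0.05) and 1 lower when adjusted over the list alone (median -0.58, camera adjusted p = 0.016; adjusted p = 0.66 with an estimated correlation). Col1a1, the main chain of type I collagen, averaged 6583 ± 5574 FPKM in NTC and 1505 ± 658 FPKM in Gli2CA (SD, n = 3 each; adjusted p = 0.094). The list lost its call without NTC replicate 1 (adjusted p = 0.27) and with the gene length trend removed (0.1). Mesenchymal transition genes gave 0 of 22 over all genes (8 at an unadjusted p under 0.05) and 4 lower when adjusted over the list alone, with a median of -0.34 (camera adjusted p = 0.049; adjusted p = 0.69 with an estimated correlation). It passed in 9 of 23 alternatives and lost the call without NTC replicate 1 (0.27) or Gli2CA replicate 2 (0.42). Tgfb2 was at -1.35 (SE 0.27), Tgfb3 at -1.08 (SE 0.26) and Tgfb1 at -1.11 (SE 0.30). All 13 tested melanocyte genes had negative estimates and 0 passed over all genes or adjusted over the list alone, with 5 at an unadjusted p under 0.05 (median -0.48, camera adjusted p = 0.016; adjusted p = 0.66 with an estimated correlation). The call was lost without Gli2CA replicate 1 (0.078) and with the length trend removed (0.12). Mitf, the melanocyte master regulator, had a log2 fold change of -0.58 (SE 0.21) and Gpnmb one of -1.48 (SE 0.53), while Tyr, Tyrp1 and Dct lay under the filter. Undifferentiated and neural crest genes gave 0 of 19 over all genes in limma (4 at an unadjusted p under 0.05), 1 lower in limma-voom (5 at an unadjusted p under 0.05) and 3 lower when adjusted over the list alone (camera adjusted p = 0.18; 0.027 without NTC replicate 3). Egfr stood at 16.2 ± 2.31 and 6.36 ± 0.362 FPKM (SD, n = 3 each; log2 fold change -1.28, SE 0.22, adjusted p = 0.05, just short of the threshold; 0.0477 in limma-voom). TGF-beta targets gave 0 of 17 over all genes (5 at an unadjusted p under 0.05), and 1 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.66).

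Skeletal muscle and adipocyte markers varied between single libraries, while some keratinocyte and red cell genes were separated by label. Of 7 tested keratinocyte genes 0 passed over all genes (3 at an unadjusted p under 0.05), and 2 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.63). The median of -0.29 differed in sign from the mean of 0.65. Krt14 stood at 0.16 ± 0.182 against 16.2 ± 13.8 FPKM (SD, n = 3 each; log2 fold change 4.10, SE 0.78, adjusted p = 0.0565). Of 18 skeletal muscle genes 0 passed in limma, also 0 at an unadjusted p under 0.05 (1 in limma-voom), over all genes or adjusted over the list alone (camera adjusted p = 0.13; 6.8e-07 without NTC replicate 3 and 0.0082 without Gli2CA replicate 2). The muscle actin gene Acta1 was at 0.131, 0.413 and 521 FPKM in NTC and 289.7, 1.85 and 71.3 FPKM in Gli2CA. Of 13 adipocyte genes 0 passed, also 0 at an unadjusted p under 0.05, over all genes or adjusted over the list alone (camera adjusted p = 0.71; 0.0084 without NTC replicate 2 and 0.047 without Gli2CA replicate 3). Adipoq was at 20.8, 0.621 and 4.63 FPKM in NTC and 2.56, 1.01 and 29.8 FPKM in Gli2CA. Red cell genes gave 0 of 7 over all genes or adjusted over the list alone (2 at an unadjusted p under 0.05) and passed camera (median 1.25, adjusted p = 0.038; adjusted p = 0.66 with an estimated correlation), a call lost without Gli2CA replicate 2 (0.28) or NTC replicate 1 (0.12). The globin gene Hbb-bs was at 34.4, 75.7 and 111 FPKM in NTC and 145, 664 and 119 FPKM in Gli2CA, and near-identical globin copies can share reads. Immediate early and heat shock genes gave 0 of 21 over all genes (3 at an unadjusted p under 0.05) and 1 lower when adjusted over the list alone (camera adjusted p = 0.48).

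**Figure D3:**
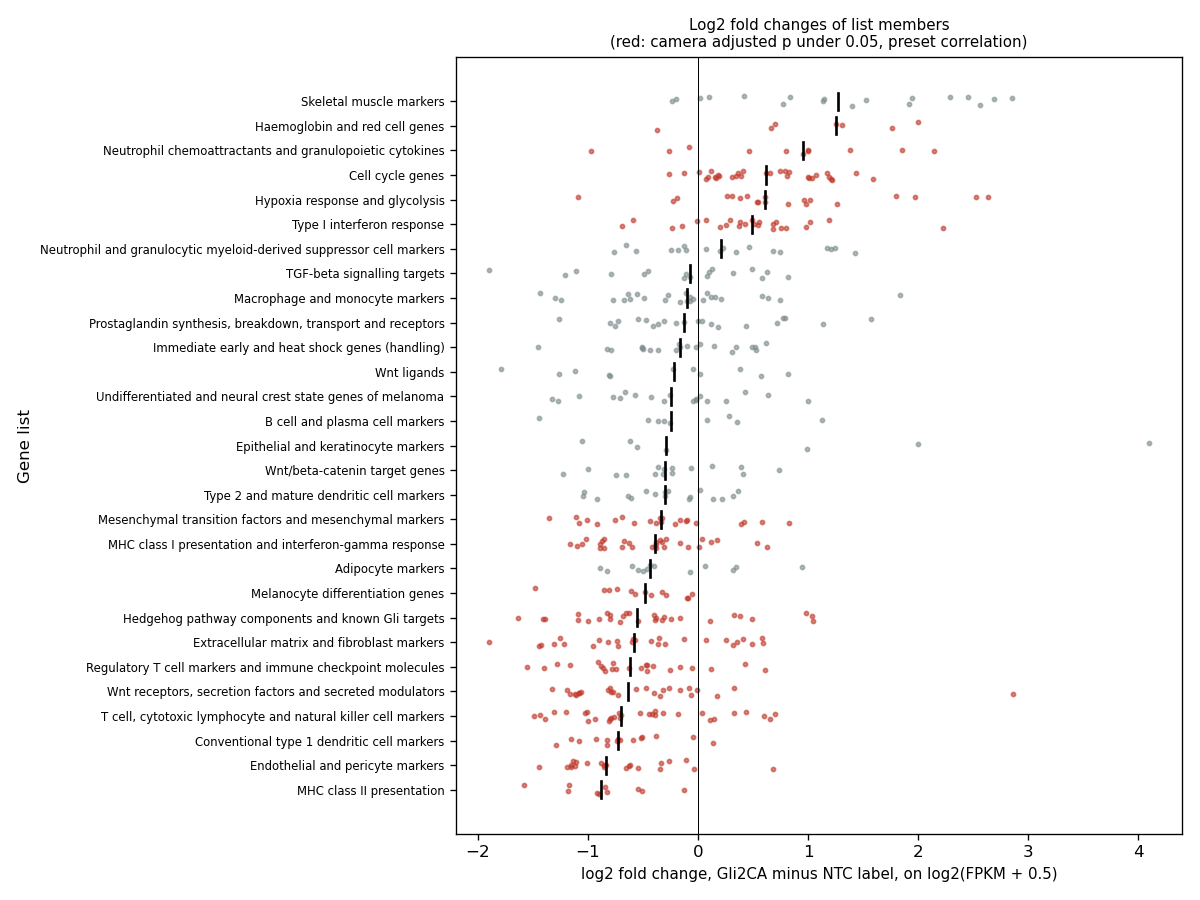
Log2 fold changes, tumors labelled Gli2CA minus NTC, on the horizontal axis for the tested members of the 29 gene lists, with 1 point per gene and a black bar at each list's median, and red for lists with a camera adjusted p under 0.05 at the preset correlation. Medians ran from -0.88 for MHC class II genes to 1.27 for skeletal muscle genes, which did not pass.

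In all, 16 of 29 lists passed camera with the preset correlation of 0.01, 5 higher and 11 lower. Other splits of the 6 samples into 3 and 3 passed 8 to 18 lists in the same way. A camera call at the preset correlation therefore does not by itself set the labels apart. With an estimated correlation 0 lists passed, and 2 had an unadjusted p under 0.05 (0.035 for neutrophil chemoattractants and 0.036 for Wnt receptors and modulators). The estimated correlation was 0.81 for cell cycle genes and 0.69 for MHC class II genes. It was -0.02 for neutrophil chemoattractants and 0.02 for Wnt receptors and modulators, near the preset value. The calls of these 2 lists were lost as well, with unadjusted camera p of 0.0028 and 0.00053 at the preset correlation. The 2 forms of camera thus differ in more than the correlation, and these 2 lists do not show why the other calls were lost. How much of the other losses came from correlation between members was not tested. Sample means overlapped between the labels for 6 of the 16 lists: T cells, type I interferon, mesenchymal transition, matrix and fibroblast, cell cycle and red cell genes. The libraries also differed in composition along with the group labels: cytosolic ribosomal protein genes took 2.97%, 4.54% and 5.31% of fragments in NTC and 6.86%, 15.2% and 8.12% in Gli2CA, and across genes the log2 fold change had a correlation of -0.36 with log2 gene length, which bears on every list above.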

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

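Limma-voom and the removal of length or GC trends were chosen after seeing the data; the other alternatives were fixed beforehand. All 55 called genes kept their direction wherever they were tested. The count of called genes, 55 (42 higher, 13 lower), was 54 with a pseudocount of 1, 44 with median-ratio scaling, 36 with quantile normalization, 55 without the variance trend, 53 with the GC trend removed and 41 with the length trend removed. The called sets were not the same: in that order they shared 53, 43, 34, 45, 43 and 33 genes with the first 55. The 97 genes called without Gli2CA replicate 2 shared 35. It was 81 with a pseudocount of 0.1, 145 with a filter at a mean FPKM of 1 (76 higher, 69 lower), 3 with no filter, 1588 with sample weights (704 higher, 884 lower), 101 with robust eBayes, 100 with limma-voom, and between 4 and 97 with 1 library left out; the cause was not tested, beyond the larger number of genes tested without a filter (35796). With protein-coding genes alone, rescaled, 737 passed, 106 higher and 631 lower (14.4% higher, against 76.4%), and the median of all tested genes moved from -0.04 to -0.29, so changes there are relative to that shift. With a replicate block, 1928 genes passed and 15 lists. The correlations of deviations between same-numbered samples were 0.35, 0.22 and 0.02. NTC replicates 1 and 2 correlated best with their own number, but NTC replicate 3 did so with Gli2CA replicate 2 (0.08). Whether same-numbered samples share a batch is therefore neither shown nor excluded. Of the lists, 16 passed, and 14 to 19 with 1 library left out, 0 with an estimated correlation, 2 with fry and 10 with the length trend removed; the causes were not tested. Some estimates, or the direction of a list's test, changed sign against the first analysis, none with an adjusted p under 0.05. With 1 library left out, Thrsp ran from -0.975 (without NTC replicate 2) to 0.013 (without NTC replicate 1) and Lpl from -1.296 to 0.026 (the same libraries). Over the same fits the list medians ran from -0.16 (without NTC replicate 1) to -0.02 (without NTC replicate 3) for prostaglandin genes, from -0.08 (without Gli2CA replicate 3) to 0.49 (without Gli2CA replicate 2) for neutrophil genes, from -1.04 (without NTC replicate 2) for adipocyte genes, from -0.22 (without NTC replicate 2) to 0.16 (without NTC replicate 3) for TGF-beta targets and from -0.25 (without Gli2CA replicate 1) for immediate early genes. Without NTC replicate 1 the list medians were 0.43 for adipocyte, -0.12 for TGF-beta and -0.04 for immediate early genes. The adipocyte median was also 0.78 with sample weights, -0.58 with protein-coding genes rescaled, and -0.17 and 0.19 without Gli2CA replicates 1 and 2. The prostaglandin median was -0.11 with no filter, -0.06 without NTC replicate 2 and -0.13 with fry. The neutrophil median was -0.07 without NTC replicate 2, and the immediate early median 0.02 without Gli2CA replicate 2 and 0.01 with the GC trend removed; the cause was not tested. At 16223343 to 22271678 fragments per sample, depth limits genes with few fragments, such as Scarna17 (18 against 1).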

Other observations

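The genes and lists of this paragraph and the next were chosen after the data were seen. As lists, ribosomal protein genes were higher and genes of the mitochondrial genome lower in the tumors labelled Gli2CA. The trend with gene length bears on these added lists too, and they were not tested with it removed. Over all tested genes the median log2 fold change was 0.49 under 500 nt and 0.35 from 500 to 1000 nt. Of 78 cytosolic ribosomal protein genes, all had positive estimates, 0 passed over all genes and 65 were higher when adjusted over the list alone (median log2 fold change 1.13, camera adjusted p = 6.4e-22 over 9 added lists; adjusted p = 0.35 with an estimated correlation). Of 13 protein-coding genes of the mitochondrial genome, 0 passed over all genes and 10 were lower when adjusted over the list alone (median -0.82, camera adjusted p = 0.00012; adjusted p = 0.35 with an estimated correlation), with mt-Nd4 at 464 ± 49.5 and 222 ± 60.9 FPKM (SD, n = 3 each). Nuclear-encoded respiratory chain genes had a positive median of 0.58 over 40 genes and proteasome core genes one of 0.58 over 14 genes, with 0 past the threshold adjusted over the list alone in either (camera adjusted p = 3.3e-05 and 5.5e-05; adjusted p = 0.35 with an estimated correlation for both). S100 genes gave 1 of 12 higher over all genes and 5 when adjusted over the list alone (median 1.05, camera adjusted p = 3.3e-05; adjusted p = 0.35 with an estimated correlation), with S100a4 at a log2 fold change of 2.17 (adjusted p = 0.0346; 0.0371 without NTC replicate 3 and 0.0549 to 0.148 without any other library). Galectin genes gave 1 of 8 higher over all genes, and 4 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.029; adjusted p = 0.35 with an estimated correlation). Mast cell genes gave 1 of 11 higher in both ways of adjusting, the protease gene Mcpt2 at 3.26 ± 0.887 and 19.1 ± 5.44 FPKM (SD, n = 3 each; adjusted p = 0.0181; 0.0256 without Gli2CA replicate 2 and 0.0539 to 0.0977 without any other library), with a camera adjusted p = 0.023 and an adjusted p = 0.35 with an estimated correlation. Schlafen genes gave 1 of 7, Slfn4, and a camera adjusted p = 0.38. Of 20 genes shared by most leukocytes, 0 passed over all genes and 11 were lower when adjusted over the list alone (median -0.72, camera adjusted p = 6.1e-05; adjusted p = 0.35 with an estimated correlation).

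The strongest calls were in genes that the naming rule leaves out. Gm773 had 1, 3 and 0 fragments in NTC and 255, 344 and 293 in Gli2CA (adjusted p = 0.000317), a ratio adjusted for depth of 243 with an exact 95% interval for counting error of 94.6 to 894, and Gm11884 had 1 fragment against 326 (ratio 356, interval 63.4 to 14100; adjusted p = 0.000779). Next to Gm773 on chromosome X, 53.3 kb between starts, 3830403N18Rik averaged 4.02 ± 1.10 and 63.5 ± 14.8 FPKM (SD, n = 3 each; adjusted p = 0.00118). These 3 genes passed in all 6 fits without 1 library, at adjusted p of 0.00143 to 0.0128. Soga3 and 9330159F19Rik, 67.8 kb between starts on chromosome 10, had log2 fold changes of -3.26 and -2.01, and the call of 9330159F19Rik held only without Gli2CA replicate 2 (0.037; 0.0593 to 0.141 without any other library).

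The count of 55 called genes and of 16 called lists was set against other ways to split the 6 samples into 3 and 3, a test fixed beforehand. Of the 10 splits, 1, the real one, called as many genes, and the highest of the others called 10. For lists, 4 of the 10 splits, the real one included, called at least 16, and the highest of the others called 18, so the list count does not set the labels apart. With 10 splits a share under 0.05 cannot be reached.

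The tests in this paragraph and the 2 that follow were chosen only after the results were seen. Gli2, Gli1, Gli3 and Ptch1 had a mean log2 change of -1.17 (SE 0.49) in the tumors labelled Gli2CA, and an effect of the active Gli2 form on them was not tested. A lower share of fibroblasts may contribute and stays open: the mean change of these 4 genes minus that of the fibroblast and matrix list was -0.69 (SE 0.67). This is barely beyond 1 standard error, a limit tightened from 2 after a value for a larger set of genes was seen, and under the first limit it would have read as a match. With the gene length trend between libraries removed the mean was -0.98 (SE 0.51), and as the 95% interval reached above 0 before the removal too, this test decides nothing. Group labels exchanged cannot be told apart from a true decrease, since 0 genes in the table are named for the construct or a tag.

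Short genes were higher and long genes lower in the tumors labelled Gli2CA: the median log2 fold change was 0.49 for genes under 500 nt and -0.43 for genes over 4000 nt, and the correlation with log2 length over genes, which are not independent replicates, was -0.36. Gli2CA replicate 2 alone does not account for it, as the correlation was -0.24 without that library. Ribosomal protein and mitochondrial genes alone do not either, as it was -0.36 over the other genes. RNA integrity or fragment size differing between libraries may be the cause and cannot be told apart from the group, since the table holds 0 values of coverage along genes. Each library's deviation had a correlation with length of 0.37, 0.25 and 0.05 in NTC and -0.01, -0.44 and -0.16 in Gli2CA, so libraries of one label also differed.

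The T cell, type 1 dendritic cell and both MHC lists were lower in the tumors labelled Gli2CA, and an effect of the Gli2 construct on immune cells was not tested. With the gene length trend between libraries removed, 4 of the 4 lists still passed camera at the preset correlation. Each had an adjusted p = 0.66 with an estimated correlation before the removal. As other splits of the 6 samples passed up to 18 lists, these passes cannot exclude the trend as a cause. The medians went from -0.7 to -0.6 for T cells and from -0.73 to -0.46 for type 1 dendritic cells. They went from -0.88 to -0.94 for MHC class II and from -0.39 to -0.49 for MHC class I. The trend as removed thus does not account for all of the medians. The removal used the mean annotated transcript length, so a length effect may remain. Fewer leukocytes overall is consistent with the mean change of 20 genes shared by most leukocytes, -0.59 (SE 0.19), which differed by -0.03 (SE 0.16) from that of the 4 lists, -0.56 (SE 0.21). Ptprc was left out of these genes because its value, 0.09 (SE 0.23), was already known, the mean with it is -0.56 (SE 0.19), and 4 of the 20, Cd53, Cd52, Cd48 and Cytip, also lay within 0.04 of 0. Fewer leukocytes of every kind, a comparison added after the one before it was seen, stays open, as the macrophage and monocyte list had a mean of -0.17 (SE 0.23), above the 4 lists by 0.38 (SE 0.20). Neutrophil markers had a mean of 0.28 and mast cell markers one of 0.71. Type 2 and mature dendritic cell markers had a mean of -0.3 and B cell and plasma cell markers one of -0.11. These means were not tested against the 4 lists.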
